A study of Hordeum vulgare with 16 samples.

How the data were processed

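Leaves of field-grown barley (Hordeum vulgare) were profiled on 16 one-colour arrays, 2 for each of 8 groups. The groups combined 4 genotypes with 2 soils. Baronesse and Golden Promise were wild-type cultivars. ChGP was Golden Promise carrying an endochitinase gene of the fungus Trichoderma harzianum. GluB carried a chimeric Bacillus (1,3-1,4)-beta-glucanase gene that had been crossed from Golden Promise into Baronesse. Soil was either untreated or inoculated with Amykor, a product with arbuscular mycorrhizal fungi. Per the labels, each sample was 100 mg of pooled leaf material from at least 10 leaves, plants were sown at 300 grains per square metre, and Cy3-labelled cRNA was made from 500 ng of total RNA. Groups, replicate numbers and pool numbers were taken from the labels. The replicates were leaf pools from the same field, so p-values measure the spread between these samples.

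Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 9.5.3.1, and the deposited scanner files held spot intensity on a linear scale. The processed intensity was background-subtracted and spatially detrended within the array, with surrogate values for dim spots, per the file headers. The same deposited files held the mean spot intensity, the local background intensity and flags of 0 or 1 for spots well above background, saturated or not uniform. A deposited table held 1 value per probe and array, a linear ratio to the probe's own median over the 16 arrays: 100.0% of the probe medians lay within 0.01 of 1. Scaling between arrays in that table is not given in the sources used here. Its 41196 probes all matched probes of the scanner files, its column medians ran from 0.858 to 1.10, and its deviations correlated with those of the scanner values at r of 0.975 to 0.989 across probes, which are not independent replicates. Columns not used numbered 0.

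The arrays held 45220 spots, of which 43803 were not controls. These made up 41196 probes, 2607 of them spotted 2 times and averaged. Each probe stood for 1 barley unigene, named here by its identifier (35_1476, for example) and by the product in the scanner files, which named one for 20367 probes. Product names are those of the array's design, often taken from a related protein of another species. No link from the unigenes to genome coordinates was used here. Spots with a non-uniformity or population outlier mark were left out. Per array, 69.6% to 77.4% of the probes were well above background, the 75th percentile of the signal ran from 604 to 936, spike-in controls fitted a line with R2 of 0.993 or more, and at most 1 probe was saturated. The number of arrays limits the precision.

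Values were log2 of the processed intensity minus the array's 75th percentile. Probes well above background on both arrays of at least 1 group were tested, 31718 in all. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model with 8 group means and no block, two-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of single probes come from limma. The model had 8 residual degrees of freedom, a moderating prior of 2.38 and a median residual SD of 0.22 on the log2 scale. Errors are standard errors of the log2 difference. Where only some arrays of a group were well above background, their number is given beside the value, and the difference rests partly on values at background. A probe not well above background on any array of a group has only a bound there. Its fold is given as "at least", the mean of the bright group over the mean of the higher of the lowest signal among probes well above background and the dim probe's own, array by array. Genotypes were compared over both soils (4 arrays against 4), within each soil (2 against 2), and in the change with Amykor (the interaction), and Amykor over the 4 genotypes (8 against 8) and within each.

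On simulated arrays built from each probe's real mean and residual spread, with independent noise (31574 probes, 200 changed), the test recovered 54.0%, 76.0%, 78.0% and 90.0% of the probes changed 2-fold for Golden Promise against Baronesse, ChGP against Golden Promise, GluB against Baronesse and Amykor. It recovered 96.0%, 96.0%, 92.0% and 100.0% of those changed 4-fold. False calls made up 3.85%, 4.97%, 5.03% and 4.04% of the calls. The noise was normal and held no slide differences, so these shares do not cover slide effects. Each comparison had a single draw, so they do not rank the comparisons.

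The design, the tests, the alternatives, the rule for named genes and 27 gene lists were fixed before the data were examined. The lists were word patterns on product names: photosystem and light harvesting, Calvin cycle and photorespiration, chitinases and beta-1,3-glucanases, (1,3-1,4)-beta-glucanases, pathogenesis-related proteins, NBS-LRR resistance genes, receptor-like kinases, jasmonate, phenylpropanoids and flavonoids, heat shock proteins, dehydrins and other drought or cold genes, phosphate, nitrogen, starch, sucrose and fructan, senescence and proteolysis, WRKY and NAC factors, glutathione S-transferases and P450, peroxidases and redox, cell wall, cytosolic ribosomal proteins, histones and cell division, transposable elements, circadian clock and flowering. As markers of other tissues, 4 more lists held wax and lipid transfer (epidermis), grain storage, root and symbiosis, and anther and pollen genes. The patterns of the pathogenesis-related and grain storage lists also matched 68 and 32 probes of other proteins, such as methionine enzymes and zinc finger proteins. These were left out after the results were seen, and both versions are given where they differ in passing. Lists with at least 5 tested probes (26) were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and comparisons. Counts of members are given over all probes and adjusted over the list alone.

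By the rule for named genes, the called probes with the same sign in both soils (for Amykor, in at least 3 of 4 genotypes) were ranked by absolute log2 difference, and the first 12 higher and 12 lower with a named product were taken, 1 probe per product. Up to 4 members of each list with the smallest p were added, called or not, and probes naming a part of a transgene.

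Slides and scan dates came from the file headers. The 16 arrays lay on 5 slides. Slides 2 and 4 held the untreated arrays of all 4 genotypes, and slide 3 held 1 Amykor array of each genotype. Slide 1 held 1 Amykor array each of Golden Promise and GluB. Slide 5, with a scan date of its own, held 1 each of Baronesse and ChGP. Genotype comparisons were therefore repeated with slide as an additive block and within slides 2, 3 and 4. No slide held both soils, so Amykor was repeated with slide as a random block (duplicateCorrelation, correlation 0.183). For single probes, the slide block given with Amykor is this random block, which cannot separate soil from slide. Alternatives also covered normexp background correction (offset 50), quantile and median scaling, the filter on dim probes, replicate number, pool and scan date as blocks, a fit on the compared groups alone, a trended and robust spread, array weights, the deposited ratios, a 2-fold threshold, and leaving out each array in turn.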

Results

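Leaf transcript levels of 4 field-grown barley genotypes were compared on 16 arrays, in untreated and in Amykor soil. Cultivar was the main axis of difference. The first principal component held 52.0% of the variance and ran from Baronesse (-107 to -94.1) through GluB (-68.7 to -31.9) to the Golden Promise background, and the second (12.7%) set GluB (55.2 to 65.4) apart. Both Golden Promise arrays from Amykor soil lay at 41.0 and 41.9 on the first component, against 95.1 and 98.6 for untreated Golden Promise and 73.7 to 92.3 for ChGP. Replicate arrays correlated at r of 0.971 (GluB in Amykor soil, SD of the differences 0.80) to 0.993 across probes, which are not independent replicates.

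**Figure D1:**
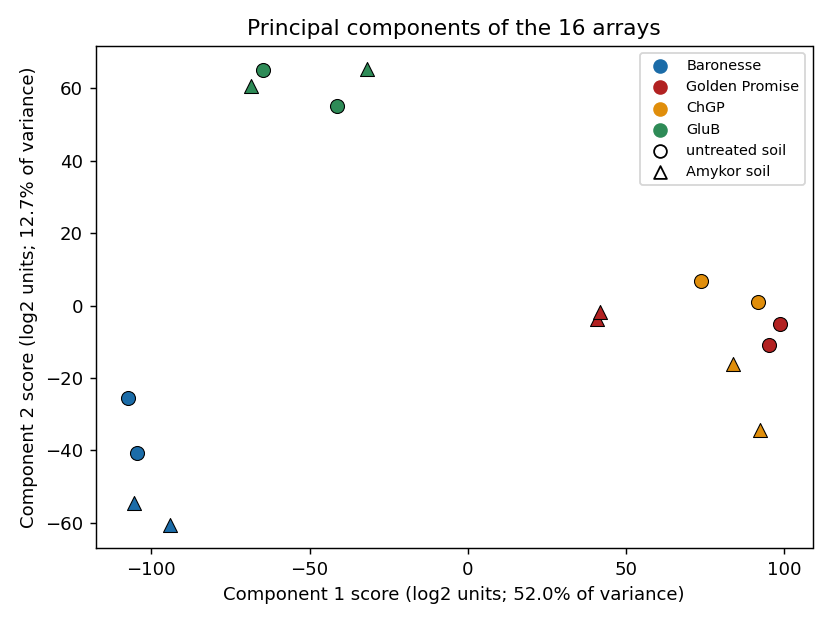
Scores of the 16 arrays on the first and second principal component of the log2 values (horizontal axis, 52.0% of the variance; vertical axis, 12.7%), coloured by genotype, with circles for untreated and triangles for Amykor soil. Baronesse lies on the left, Golden Promise and ChGP on the right, GluB at the top, and both Golden Promise arrays from Amykor soil at 41.0 and 41.9, away from untreated Golden Promise.

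Golden Promise and Baronesse differed in probes of defence genes, chlorophyll-binding proteins, dehydrins and enzymes of secondary metabolism, among others. Thaumatin-like protein TLP5 (35_14141), of an antifungal protein family, was higher in Golden Promise by 10.37 ± 1.18 on the log2 scale (adjusted p = 9.7e-05, 4 arrays against 4). Beta-cyanoalanine synthase (35_14705), which detoxifies cyanide, was higher by 9.67 ± 0.85 (1.4e-05). Pathogenesis-related protein 4 (35_17228) was at least 683-fold lower in Golden Promise (3.4e-07). A serine/threonine receptor-like kinase (35_22781) was at least 672-fold lower (3.1e-08), also with no Golden Promise array well above background. In limma, 9392 of 31718 probes (29.6%) passed, 4255 higher and 5137 lower in Golden Promise. Of these, 3648 differed 2-fold or more.

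Among the other probes named by rule, early nodulin 8 (35_1476) was at least 2236-fold, a heat shock factor (35_4310) at least 821-fold and a ubiquitin-conjugating enzyme (35_16398) at least 398-fold higher in Golden Promise. A UDP-glucosyltransferase (35_3491) was higher by 9.93 ± 0.39 (1 of 4 Baronesse arrays well above background). A one helix protein of the light-harvesting family (35_4416) differed by 9.32 ± 0.75 and a GAMYB-binding protein (35_1178) by 9.26 ± 0.63 (1 of 4 Baronesse arrays each). Lower in Golden Promise were an actin interacting protein (35_7183, at least 327-fold), an HMG1/2-like chromatin protein (35_49818, at least 286-fold), fatty aldehyde dehydrogenase 1 (35_7837, at least 85.3-fold) and a proline-rich protein measured on all arrays (35_6360, -7.80 ± 0.20). A probe that is dark in 1 cultivar does not separate low expression from a sequence difference under the probe.

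Defence genes went both ways. Of 89 pathogenesis-related probes 25 were higher and 16 lower in Golden Promise (28 and 16 adjusted over the list alone). The list's median was 0.25 (adjusted p = 0.014, 0.89 with an estimated correlation), and 0.36, 0.14 and 0.26 within slides. With 68 wrongly matched probes such as methionine enzymes and histone H4 put back, which were left out after the results were seen, 40 were higher and 37 lower of 157 (adjusted p = 0.27). Salicylate-responsive PR-1 was the clearest: 35_15378 differed by 9.53 ± 0.58 (2 of 4 Baronesse arrays well above background), 35_38976 by 8.84 ± 0.37, 35_15377 by 8.83 ± 0.37 and 35_15380 by 3.40 ± 0.14. A type-1 relative (35_35113) was lower (-3.50 ± 0.18, 2 of 4 Golden Promise arrays). Of 172 NBS-LRR resistance probes 33 were higher and 35 lower (36 and 39 alone, adjusted p = 0.72). Intracellular receptors of the Mla locus, where barley cultivars carry different alleles for powdery mildew resistance, were among both. MLA7 (35_10730) was at least 29.5-fold higher, and MLA1 (35_27729) was lower (-7.04 ± 0.47, 1 of 4 Golden Promise arrays well above background). An RPM1-like probe (35_23986) was at least 163-fold and an NB-ARC probe (35_26501) at least 223-fold lower. Receptor-like kinases (27 higher, 42 lower of 209, 33 and 51 alone, adjusted p = 0.70) included 35_13331, at least 68.4-fold higher. Chitinases and beta-1,3-glucanases (17 and 21 of 76, 19 and 23 alone, adjusted p = 0.70) included a chitinase (35_5670, 1.43 ± 0.19), glucanase GI (35_406, 1.20 ± 0.13) and an elicitor-inducible glucanase (35_21069, -3.61 ± 0.27).

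Photosystem and light-harvesting genes were lower in Golden Promise. Of 108, 67 fell and 6 rose (73 and 10 alone, median -0.61, adjusted p = 1.2e-07, 0.90 with an estimated correlation). The median was -0.99 in untreated and -0.19 in Amykor soil. Within slides 2, 3 and 4 it was -0.98, -0.22 and -0.99. Probes of chlorophyll a-b binding protein 3C split, with 35_450 lower (-3.22 ± 0.36), 35_28166 63.8-fold higher and 35_407 at least 99.7-fold higher. Dehydrins and other drought or cold genes, which protect cells during dehydration, were lower in 35 of 67 and higher in 0 (42 and 0 alone, median -0.57, adjusted p = 1.2e-07, 0.18 with an estimated correlation). Its medians within slides were -0.62, -0.68 and -0.54. Dehydrin 35_14544 was at least 16.7-fold lower. Dehydrin 35_14536 differed by -3.88 ± 0.46 (3 of 4 Golden Promise arrays well above background) and a low temperature induced protein (35_3084) by -4.28 ± 0.35 (2 of 4).

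Histones and cell division genes were lower in 79 of 218 and higher in 29 (87 and 31 alone, median -0.32, adjusted p = 0.011, 0.87 with an estimated correlation). H2AX (35_13933) differed by -2.02 ± 0.16 and H3 (35_14069) by -1.57 ± 0.14. The list's medians within slides were -0.41, -0.20 and -0.39, and with 1 probe per product the shift did not pass (adjusted p = 0.89). Glutathione S-transferases, P450s and glucosyltransferases, which modify toxins and secondary metabolites, were higher in 88 of 319 and lower in 45 (96 and 50 alone, median 0.13, adjusted p = 0.038, 0.90 with an estimated correlation). Within slides the medians were 0.24, 0.09 and 0.21, and with quantile scaling the adjusted p was 0.059. CYP99A1 (35_22055) differed by 5.58 ± 0.24 and a glucosyltransferase (35_17121) by 4.20 ± 0.18 (3 of 4 Baronesse arrays well above background).

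The other lists, grain storage apart, held changed members without a shift that passed. Flavonoid and phenylpropanoid genes (33 higher, 15 lower of 125, adjusted p = 0.12) included chalcone isomerase (35_2840, 6.60 ± 0.50, 1 of 4 Baronesse arrays well above background) and anthocyanidin synthase (35_36839, 3.55 ± 0.24), which act in pigment synthesis. Starch, sucrose and fructan genes (17 and 16 of 106, 0.70) included sucrose synthase 2 (35_14483, -3.72 ± 0.36) and fructan 6-exohydrolase (35_2597, -2.94 ± 0.23). Phosphate genes (4 and 4 of 43, 0.88) included an acid phosphatase (35_547, -6.69 ± 0.58, 3 of 4 Golden Promise arrays) and phosphate transporter 1-4 (35_420, -2.95 ± 0.28). Root and symbiosis genes (7 and 8 of 73, 0.70) included nicotianamine synthase-like probes (35_11279, 1.34 ± 0.08; 35_28024, 1.32 ± 0.08), which make an iron chelator. Wax and lipid transfer genes (8 and 17 of 53, 0.63) included a lipid transfer protein (35_16799, -2.58 ± 0.30) and cell wall genes (20 and 50 of 178, 0.24) a pectin glucuronyltransferase (35_22764, -3.77 ± 0.16, 2 of 4 Golden Promise arrays). Grain storage genes, markers of another tissue, were lower in 12 of 41 and higher in 1 (12 and 1 alone, median -0.41, adjusted p = 0.016, 0.31 with an estimated correlation). Their medians within slides were -0.42, -0.23 and -0.44. Protein Z (35_14790) was at least 5.30-fold lower, and with 32 wrongly matched probes put back, also left out after the results were seen, the list did not pass (8 higher, 14 lower of 73, 0.52). Senescence genes (7 and 15 of 88, 0.78) included 35_20834, at least 68.6-fold lower, and ribosomal proteins (44 and 41 of 392, 0.92) S17 (35_16998, 5.08 ± 0.30).

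Of the 687 tested probes whose product name came from a filamentous fungus, 402 were higher in Golden Promise and 36 lower (58.5% higher, against 12.4% of the other probes; median 1.73). The median was 2.30 in untreated soil (371 higher, 24 lower) and 1.12 in Amykor soil (76 and 22). The Golden Promise calls had the same sign within slides 2, 3 and 4 in 98.2%, 94.5% and 97.7%. The calls were made with these same arrays, so agreement in sign is largely fixed by the selection. A slide block called 10654 probes, and normexp background correction called 3076. The cultivars differed in 8507 probes in untreated and 4624 in Amykor soil. Of these, 2896 were called in both soils (1240 if independent), 2790 with the same sign. The counts by soil ran from 4595 to 10075 and from 2304 to 6140 with 1 array left out.

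**Figure D2:**
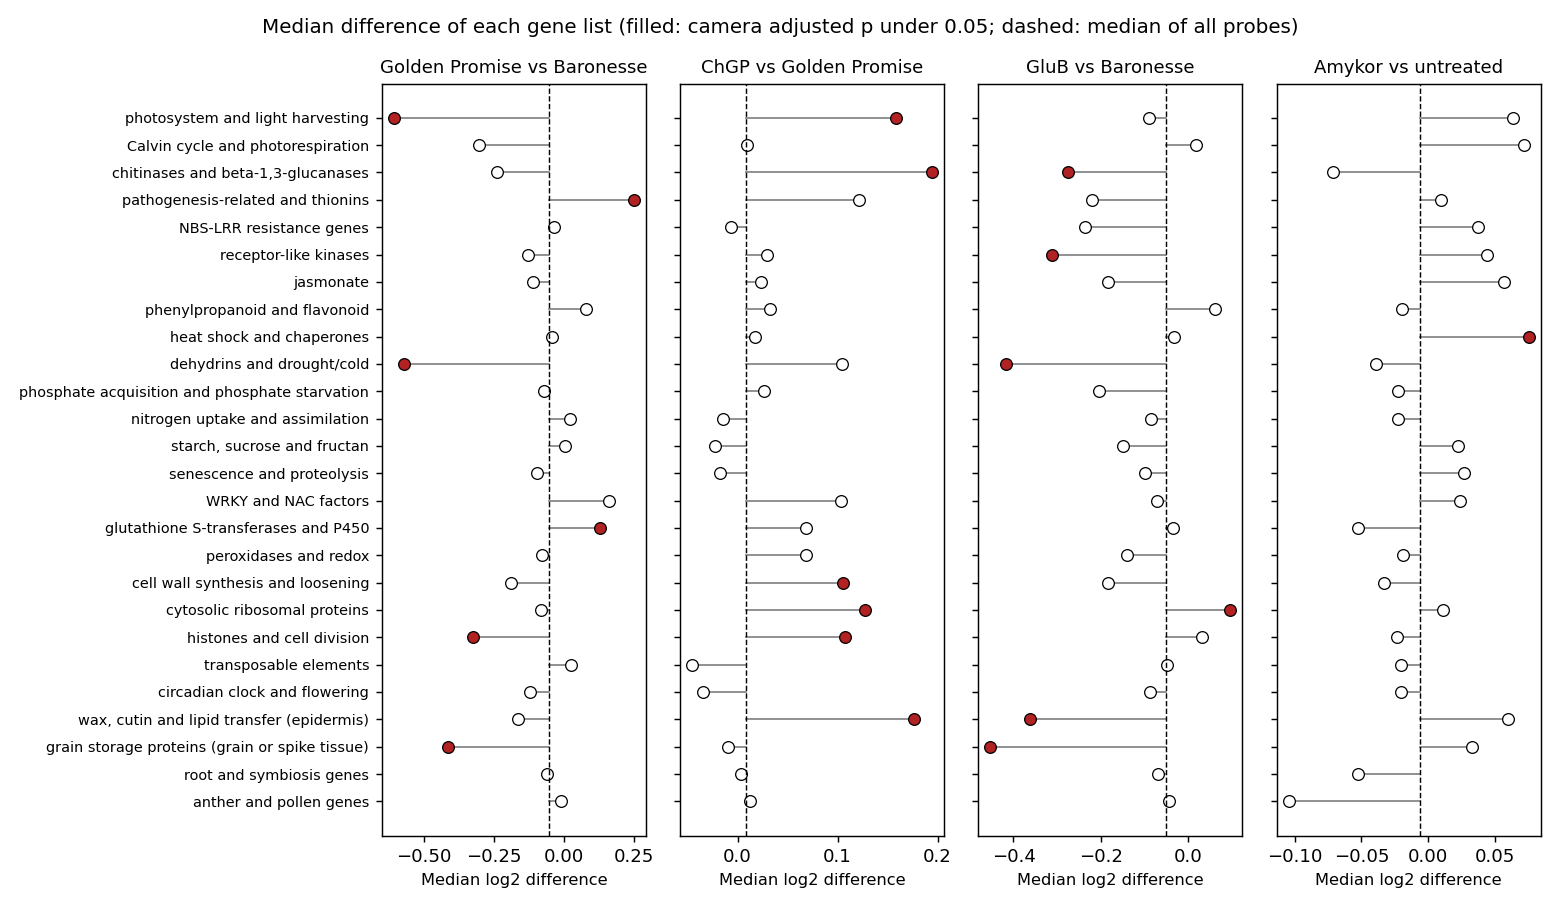
Median log2 difference of the tested probes of each of 26 gene lists (horizontal axis) in the 4 main comparisons, filled where camera's adjusted p passed, with the median of all probes as a dashed line. Golden Promise was lowest against Baronesse in the photosystem (-0.61) and dehydrin (-0.57) lists, GluB in the grain storage (-0.45) and dehydrin (-0.42) lists, and shifts with Amykor were small (0.08 for heat shock proteins).

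ChGP and Golden Promise, the endochitinase line and its own cultivar, differed in few probes. Among the probes named by rule, the largest rise was a CACTA transposon probe (35_36305, 7.78 ± 0.76, adjusted p = 4.0e-04, 4 arrays against 4, 2 of 4 Golden Promise arrays well above background). A Ulp1 protease, which removes SUMO from proteins (35_50182), was at least 37.4-fold higher in ChGP (1.4e-06) and a caspase-like peptidase C14 (35_24409) at least 32.2-fold higher (4.8e-05). A ribosomal protein-like probe (35_23726) was higher by 3.91 ± 0.19 (1.4e-06) and a RelA/SpoT protein (35_20836), of a family that makes the alarmone ppGpp, by 3.20 ± 0.28 (2.3e-04). In limma 402 of 31718 probes passed, 170 higher and 232 lower. Of these, 257 differed 2-fold or more.

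Chitinase and beta-1,3-glucanase genes of barley itself shifted as a list, although 0 of its 76 members passed over all probes and 0 alone in limma (17 at an unadjusted p under 0.05). Its median was 0.19 (adjusted p = 2.3e-06, 0.22 with an estimated correlation), and 0.22, 0.31 and 0.15 within slides. Values of its members that did not pass were 0.96 ± 0.24 and 0.99 ± 0.26 for chitinase IV (35_15621 and 35_15622, adjusted p = 0.12 and 0.14). They were 0.93 ± 0.23 for a glucan endo-1,3-beta-glucosidase (35_234, 0.13) and 0.45 ± 0.10 for an elicitor-inducible glucanase (35_9752, 0.076). Pathogenesis-related genes (3 higher and 1 lower of 89, 7 and 3 alone, adjusted p = 0.16) included 35_16614 (1.03 ± 0.09) and 35_18110 (1.09 ± 0.15). A pathogen-related protein outside the list (35_31051) was higher by 2.62 ± 0.28. Without both Golden Promise Amykor arrays, which leaves the difference in untreated soil alone (2 arrays against 2), 35_18110 (0.82, 0.20) and 35_31051 (2.35, 0.084) did not pass.

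Photosystem genes (1 higher, 1 lower of 108, 1 and 1 alone) had a median of 0.16 (adjusted p = 2.9e-04, 0.90 with an estimated correlation). That median was 0.48 in untreated and -0.22 in Amykor soil (within slides 0.64, -0.03 and 0.35). The members were a plastocyanin-like protein (35_4524, 1.31 ± 0.10) and a chlorophyll a/b-binding protein (35_6668, -1.30 ± 0.22, adjusted p = 0.14 with a slide block). Ribosomal proteins (1 and 2 of 392, 1 and 2 alone, median 0.13, adjusted p = 1.1e-05, 0.90 with an estimated correlation) had medians of 0.26, -0.04 and 0.21 within slides and did not pass with a slide block (0.19). Histones and cell division genes shifted too (5 and 1 of 218, 8 and 1 alone, median 0.11, adjusted p = 8.1e-04, 0.87 with an estimated correlation). Their medians within slides were 0.23, 0.01 and 0.13, and they included H3 (35_14053, 5.73 ± 0.61, 1 of 4 Golden Promise arrays well above background) and H2B (35_13980, -1.19 ± 0.18, 2 of 4 ChGP arrays). So did wax and lipid transfer genes (1 and 0 of 53, 3 and 0 alone, median 0.18, adjusted p = 0.0017, 0.87 with an estimated correlation). Their medians within slides were 0.35, -0.04 and 0.13, and they included a lipid transfer protein (35_613, 1.33 ± 0.20, 3 of 4 Golden Promise arrays, but -0.22 with normexp). So did cell wall genes (1 and 1 of 178, 1 and 1 alone, median 0.11, adjusted p = 0.030, 0.90 with an estimated correlation). Their medians within slides were 0.18, 0.16 and 0.08, and they included a xyloglucan fucosyltransferase (35_3627, 0.74 ± 0.15), which did not pass with a slide block (0.19) or without both Golden Promise Amykor arrays (0.63).

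Most of the falls in ChGP named by rule were at probes well above background on both Golden Promise arrays from Amykor soil and on no other array of the pair of genotypes. Among them was a cation/hydrogen exchanger (35_3328, at least 12.3-fold lower). Others were a flavonol sulfotransferase (35_4431, at least 11.7-fold), a protein kinase (35_5850, at least 6.68-fold), a cysteine proteinase (35_10969, at least 6.60-fold), MLA7 (35_2871, at least 5.13-fold, slide block 0.14) and MLA6-2 (35_2872, at least 5.33-fold). These folds average both soils and describe neither. In untreated soil both genotypes were at background at these probes, with log2 differences of -0.78 to -0.003. In Amykor soil, with ChGP at background, the differences were -8.33 to -6.06. A calcium-dependent protein kinase (35_6919) was lower in both soils (-6.33 ± 1.08, adjusted p = 0.016, 2 of 4 ChGP arrays). It was about as large with a slide block and without both Golden Promise Amykor arrays (-5.57 and -6.43), without passing (0.10 and 0.27). Without both Golden Promise arrays from Amykor soil, a setting chosen after seeing the data, 68 probes passed, 54 higher and 14 lower. That setting compared the genotypes in untreated soil alone (2 arrays against 2), so the ChGP Amykor arrays also left the difference. Calls lost there mix the change of soil with the loss of arrays. The CACTA probe 35_36305 was at 6.70 there, with an adjusted p of 0.061 from fewer arrays. Calls fell to 260 without the first untreated or the first Amykor array of Golden Promise and to 261 without the second Amykor array of ChGP. The lone array of a group is then assumed to vary like the others.

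Calls, made with these same arrays, had the same sign within slides 2, 3 and 4 in 80.6%, 99.5% and 92.0%. A slide block called 291 probes, and normexp background correction called 93. ChGP and Golden Promise differed in 100 probes in untreated and 418 in Amykor soil, with 64 called in both (1.3 if independent), 62 of the same sign. Leaving out 1 array gave 26 to 200 and 188 to 592, and on the compared groups alone untreated soil called 0 (2950 at an unadjusted p under 0.05 in limma). No probe of the array named the endochitinase, the bacterial glucanase or a selection marker (0 each), so neither transgene's transcript was identified. The search was by product name, given for 20367 of 41196 probes, and probe sequences were not searched.

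GluB, the glucanase line, and Baronesse differed in single PR-1 and resistance gene probes and, at camera's preset correlation, in the lists of receptor kinases and dehydrins (adjusted p of 0.18 and 0.42 with an estimated correlation). One helix protein (35_4416) was higher in GluB by 9.88 ± 0.75 (adjusted p = 1.2e-05, 4 arrays against 4; 1 of 4 Baronesse arrays well above background) and PR-1 by 8.87 ± 0.58 (35_15378, 2 of 4 Baronesse arrays well above background). Nitrilase 2 (35_17606), which converts nitriles to acids, was higher by 8.75 ± 0.62 and chalcone isomerase (35_2840) by 8.01 ± 0.50 (1 of 4 Baronesse arrays each). A dephospho-CoA kinase (35_18644), the last step of coenzyme A synthesis, differed by -9.53 ± 0.95, and ferredoxin-sulfite reductase (35_49438), of sulfur assimilation, differed by -7.07 ± 0.45 (1 of 4 GluB arrays each). In limma 3987 of 31714 probes passed, 1756 higher and 2231 lower. Of these, 1321 differed 2-fold or more.

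Receptor-like kinases were lower in 55 of 209 and higher in 11 (70 and 15 alone, median -0.31, adjusted p = 5.1e-05, 0.18 with an estimated correlation). Within slides the median was -0.18, -0.37 and -0.04. Kinase LRK10 (35_3296) differed by -5.26 ± 1.17 (3 of 4 GluB arrays well above background) and an S-receptor-like kinase (35_43473) by -1.55 ± 0.13, while 35_13331 was at least 39.2-fold and 35_26567 at least 17.7-fold higher. Dehydrins and other drought or cold genes were lower in 14 of 67 and higher in 0 (16 and 0 alone, median -0.42, adjusted p = 1.6e-04, 0.42 with an estimated correlation). Medians within slides were -0.23, -0.55 and -0.23, and members included 35_14536 (-3.42 ± 0.46, 3 of 4 GluB arrays) and DHN4 (35_14532, -3.43 ± 0.48, 2 of 4). Chitinases and beta-1,3-glucanases were lower in 17 of 76 and higher in 6 (20 and 6 alone, median -0.28, adjusted p = 0.038, 0.87 with an estimated correlation). With a slide block the adjusted p was 0.051, and the medians within slides were -0.42, -0.20 and -0.25. Glucanase GIV (35_13456) differed by -2.24 ± 0.26 (2 of 4 GluB arrays), 35_234 by -1.89 ± 0.23 and a chitinase (35_14361) by 0.84 ± 0.10.

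Wax and lipid transfer genes, which build the leaf surface, were lower in 8 of 53 and higher in 2 (16 and 2 alone, median -0.36, adjusted p = 0.011, 0.87 with an estimated correlation). Medians within slides were -0.50, -0.49 and -0.33, with a wax synthase (35_9508) at -0.97 ± 0.15 and glossy1 (35_18836) at 1.09 ± 0.12. Grain storage genes were lower in 14 of 41 and higher in 2 (18 and 2 alone, median -0.45, adjusted p = 0.0023, 0.18 with an estimated correlation). Their medians within slides were -0.42, -0.68 and -0.47, and B1-hordein (35_302) was at least 2.70-fold and gamma-hordein (35_216) at least 2.01-fold lower. With the wrongly matched probes put back the list did not pass (4 higher, 16 lower of 73, 0.21). Pathogenesis-related genes (8 higher, 16 lower of 89, 9 and 21 alone) had an adjusted p of 0.20. Ribosomal proteins were higher in 19 of 392 and lower in 6 (12 and 2 alone, median 0.10, adjusted p = 0.0026, 0.90 with an estimated correlation). Their median was -0.25 in untreated and 0.45 in Amykor soil (within slides -0.23, 0.74 and -0.27). L40 (35_13886) differed by 3.22 ± 0.13 and L30 (35_13681) by 1.81 ± 0.11. NBS-LRR genes (15 higher, 33 lower of 172, 16 and 40 alone, adjusted p = 0.11) included MLA7 (35_10730, at least 21.0-fold higher), a resistance protein (35_47494, 8.003 ± 0.44, 1 of 4 Baronesse arrays) and an RPM1-like probe (35_23986, -5.30 ± 0.73, 2 of 4 GluB arrays). A senescence-associated protein (35_20834) was at least 56.1-fold and a Myb factor (35_47830) at least 45.2-fold lower. Sucrose synthase 2 (35_14483) differed by -5.40 ± 0.36 (3 of 4 GluB arrays), and GST 31 (35_2367) was at least 3.72-fold higher.

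Of the 3987 GluB calls, 3543 (88.9%) had the sign of Golden Promise minus Baronesse. Both differences share the Baronesse arrays, and shared controls alone gave 86.6% on average in simulations (highest 87.7%). These simulations held noise without group differences. Over all probes the covariance of both differences was 0.413, against 0.028 on average in the simulations (highest 0.032), so shared noise alone does not give it. With split controls the share was 84.9% (999 of 1176, binomial p = 1.7e-139 across probes) for GluB in untreated soil against Golden Promise in Amykor soil, and 56.5% (2380 of 4209, 2.1e-17) the other way round. Both comparisons called 1134 probes higher and 1287 lower, and 117 in opposite directions. With the same split controls they called 766 in common, 725 of the same sign (85.7 if independent) and 41 opposite, and the other way round 1814, 1195 of the same sign (567) and 619 opposite. Fungus-named probes did not follow (8 higher and 29 lower of 687, median -0.26). Split controls remove shared noise but not the shared Baronesse genotype: a probe at which Baronesse alone differs gives the same sign in both comparisons. The binomial p and the values if independent do not allow for such probes, so they do not show that GluB resembles Golden Promise.

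GluB and Baronesse differed in 1176 probes in untreated and 4209 in Amykor soil. Both soils called 798 (156 if independent), 779 of the same sign. Without 1 array in turn, the soils called 569 to 1777 and 2717 to 6403. Calls, made with these same arrays, had the same sign within slides 2, 3 and 4 in 96.8%, 98.0% and 94.3%, and a slide block called 4963 probes. Calls fell to 2162 without the first untreated Baronesse array, to 2611 and 2360 without the first and second untreated GluB array, and rose to 6237 without the first GluB Amykor array. They numbered 1777 without both GluB Amykor arrays (chosen after seeing the data, and in untreated soil alone), 1674 from the compared groups alone and 832 with normexp.

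Between Amykor and untreated soil, which lay on different slides, single probes of stress and cell wall genes differed. Nitrate reductase passed too, but not with the slide block (adjusted p = 0.081). A germin-like protein (35_147), of a cell wall family linked to oxidative defence, was lower in all 4 genotypes (-2.13 ± 0.19, adjusted p = 5.0e-04, 8 arrays against 8, 7 of 8 Amykor arrays well above background, slide block 0.0033). A xyloglucan endotransglycosylase (35_480), which remodels walls, differed by -0.99 ± 0.09 over the 4 genotypes (5.8e-04, slide block 0.0033). An NBS-LRR protein (35_24551) was higher in all 4 (2.57 ± 0.27, 0.0014, 7 of 8 untreated arrays, slide block 0.010). A receptor-like kinase (35_5301) was higher by 1.56 ± 0.11 (1.0e-04, slide block 8.2e-04), with 2.03 in Baronesse, 2.25 in Golden Promise, 1.91 in ChGP and 0.04 in GluB. In limma 853 of 31714 probes passed, 532 higher and 321 lower. Of these, 167 differed 2-fold or more.

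Nitrate reductase (35_6525), the first step of nitrate assimilation, was lower (-2.05 ± 0.35, adjusted p = 0.014, slide block 0.081), with -4.42, -2.19, -1.46 and -0.15 in Baronesse, Golden Promise, ChGP and GluB. Glutamate decarboxylase (35_14142, -1.70 ± 0.26), alpha-galactosidase (35_28084, -1.65 ± 0.22), xylanase inhibitor XIP-III (35_849, -1.61 ± 0.25), a ferredoxin (35_29801, -1.53 ± 0.23) and a Myb factor (35_30538, -2.47 ± 0.30, 4 of 8 Amykor and 7 of 8 untreated arrays well above background) fell too, with 0.034, 0.022, 0.0499, 0.038 and 0.016 under the slide block. Glutaredoxin-C1 (35_12387, -3.23 ± 0.50, 1 of 8 Amykor and 5 of 8 untreated arrays) and glutaredoxin-C14 (35_39570, -2.74 ± 0.45, 2 of 8 and 6 of 8), small redox proteins, were also lower (slide block 0.043 and 0.049). Soluble acid invertase (35_4), which splits sucrose, was higher (3.01 ± 0.55, 0.019, 7 of 8 untreated arrays, slide block 0.091), at 3.00, 4.11, 5.51 and -0.58 in the same genotypes. A defensin (35_17029, 2.41 ± 0.38, 0.011, 6 of 8 Amykor and 4 of 8 untreated arrays, slide block 0.052) was at 1.89, 6.29, 2.56 and -1.10 in these. A low temperature induced protein (35_3084, 1.88 ± 0.25, 0.0044, 4 of 8 untreated arrays, slide block 0.031) was at 0.79, 2.80, 2.62 and 1.30. For both, untreated Golden Promise and ChGP were at background, as was the defensin in GluB in Amykor soil, so those values depend on the background level. Without both Golden Promise Amykor arrays (chosen after seeing the data), alpha-galactosidase and the Myb factor passed (0.017 and 0.035). The other probes of this paragraph did not (0.067 to 0.31). Nitrate reductase was at -2.01, glutamate decarboxylase at -1.70, the ferredoxin at -1.46, XIP-III at -1.345 and invertase at 2.645. Glutaredoxin-C1 and C14 were at -2.34 and -1.87, the low temperature induced protein at 1.57 and the defensin at 1.12.

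By fry 0 lists passed for a shift in 1 direction, and 23 of 26 in its mixed test, which counts changes in both directions. Heat shock proteins and chaperones passed at camera's preset correlation with a small shift. Of 214, 7 were higher and 0 lower (12 and 0 alone, median 0.08, adjusted p = 0.0059, 0.87 with an estimated correlation). HSP17.8 differed by 0.79 ± 0.13 (35_15452) and 0.90 ± 0.18 (35_15451), with 0.065 and 0.12 under the slide block. Phosphate genes, which respond to mycorrhiza in roots, held 1 higher and 2 lower of 43 (1 and 3 alone, adjusted p = 0.51). These were a phosphate transporter (35_50618, 0.62 ± 0.11), a purple acid phosphatase (35_7536, -1.03 ± 0.16) and an SPX protein (35_22331, -0.48 ± 0.07). Under the slide block, the first 2 did not pass (0.064 and 0.0501, against 0.035 for the SPX protein). Starch, sucrose and fructan genes (4 and 1 of 106, 6 and 2 alone, 0.37) included vacuolar invertase (35_369, 0.51 ± 0.07, slide block 0.025) and sucrose-phosphate synthase 5 (35_22682, -1.45 ± 0.26, slide block 0.090). Flavonoid genes (3 and 4 of 125, 3 and 5 alone, 0.76) included dihydroflavonol reductases (35_15396, -0.60 ± 0.10; 35_50694, -0.57 ± 0.10), which did not pass under the slide block (0.052 and 0.063). Pathogenesis-related genes held 3 higher and 1 lower of 89 (5 and 2 alone, 0.97). Root and symbiosis genes held 0 higher and 0 lower of 73 (0.51) in limma, with 10 at an unadjusted p under 0.05, and ribosomal proteins 3 and 4 of 392 (0 and 4 alone; 0.63), such as S5 (35_34592, -1.05 ± 0.12, slide block 0.016). Without both Golden Promise Amykor arrays, 35_7536, 35_369 and 35_34592 passed among the named probes of these lists, and the others had adjusted p of 0.053 to 0.11. Their sizes there were 0.90 (35_15452), 0.87 (35_15451), 0.63 (35_50618), -0.39 (35_22331), -1.59 (35_22682), -0.56 (35_15396) and -0.50 (35_50694).

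**Figure D3:**
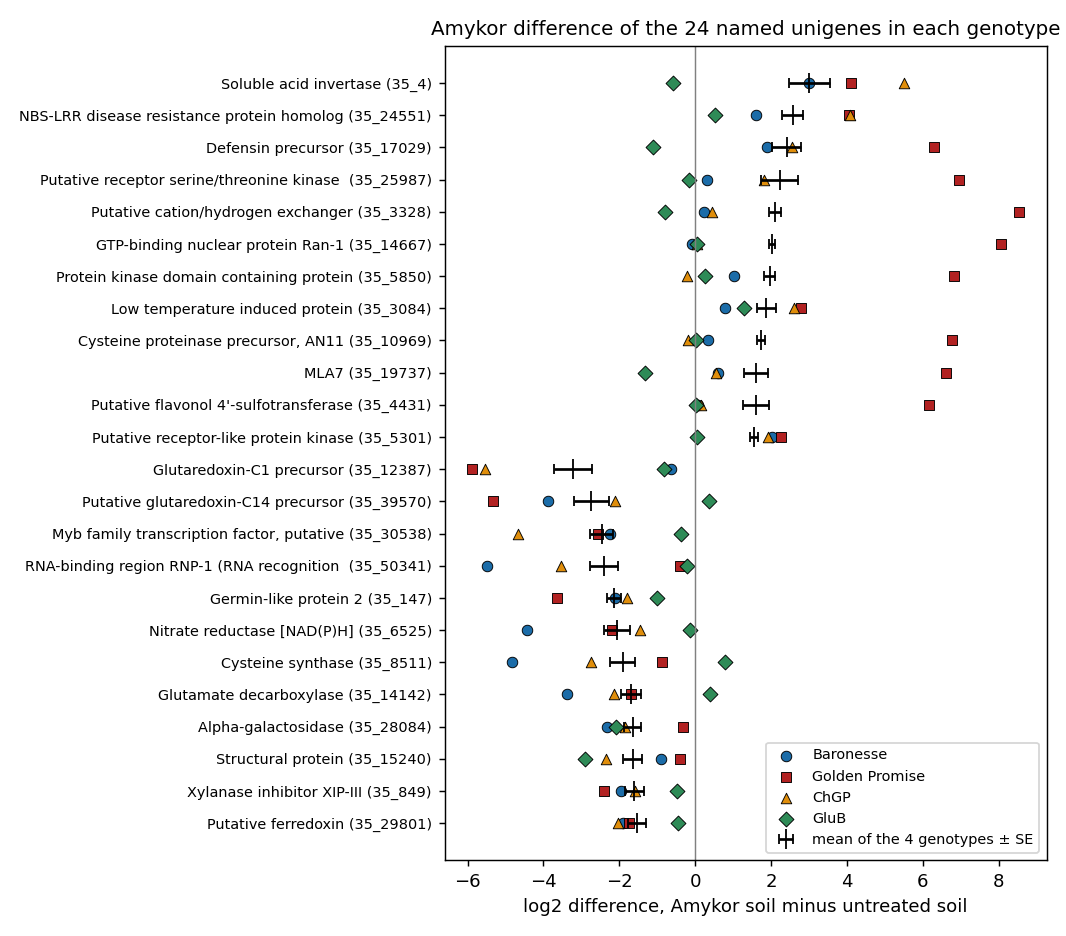
Log2 difference between Amykor and untreated soil (horizontal axis) of the 24 unigenes named by rule, as 1 point per genotype and the mean of the 4 genotypes with its standard error. Germin-like protein 2 lies below 0 in all 4 genotypes (mean -2.13), while Ran-1 lies at 8.07 in Golden Promise, where untreated arrays were at background, and near 0 in the others.

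Several of the mean rises named by rule were at probes at background on both untreated Golden Promise arrays and well above it on both Amykor arrays. These were Ran-1 (35_14667, at least 244-fold higher), the cation/hydrogen exchanger (35_3328, at least 342-fold), the protein kinase (35_5850, at least 113-fold) and the cysteine proteinase (35_10969, at least 110-fold). No ChGP array was well above background at these probes, and no Baronesse or GluB array at 35_3328. At the others all Baronesse and GluB arrays were, with changes of -0.07 and 0.06 for Ran-1, 1.03 and 0.25 for 35_5850 and 0.34 and 0.01 for 35_10969. The change with Amykor differed between Golden Promise and Baronesse in 1223 probes (913 higher, 310 lower), between ChGP and Golden Promise in 143 (6 and 137) and between GluB and Baronesse in 56 (41 and 15). These ran from 220 to 2672, 88 to 294 and 2 to 2002 with 1 array left out, and were 875, 88 and 82 with a slide block. Within genotypes, 928 probes passed in Baronesse (377 higher, 551 lower), 714 in Golden Promise (561 and 153), 42 in ChGP (21 and 21) and 1 in GluB (with 2041 at an unadjusted p under 0.05). These counts depended on single arrays. They fell to 38 without the first untreated Baronesse array, 197 without the second Golden Promise Amykor array and 3 without the second untreated ChGP array. Without the first GluB Amykor array they were 2009, 1680, 128 and 862. On the compared groups alone they were 0, 1168, 8 and 0 (5287 and 985 unadjusted in Baronesse and GluB), so the counts do not rank the genotypes. The 1 probe, named after its value was seen, was an NBS-LRR protein (35_9342, -2.95 ± 0.25, adjusted p = 0.0085). Baronesse and Golden Promise shared 56 (20.9 if independent), 36 of the same sign. Baronesse and ChGP shared 14, all of the same sign (1.2), and Golden Promise and ChGP 18, all of the same sign (0.95). Baronesse and ChGP lay on the same slides in both soils, and Golden Promise shared slides 2, 3 and 4 with them. Slide differences can therefore add to these overlaps, which the values if independent leave out.

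Among 164 probes well above background in untreated Baronesse, at background in untreated Golden Promise and at least 16-fold apart, 83 were well above background on both Golden Promise arrays from Amykor soil. Soil and slide went together, so Amykor differences also hold slide differences: with slide as a random block 228 probes passed. Without both Golden Promise Amykor arrays 137 passed (chosen after seeing the data), and normexp called 74. Leaving out 1 array moved the count by over 1.5 times for 12 of the 16 arrays. It was 476 and 434 without the first and second untreated Baronesse array, 500 without the first untreated ChGP array, 444 without the second ChGP Amykor array and 543 and 454 without the untreated GluB arrays. It was 439 and 502 without the untreated Golden Promise arrays, 454 and 392 without the Golden Promise Amykor arrays, and 1414 and 1644 without the GluB Amykor arrays.

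**Figure D4:**
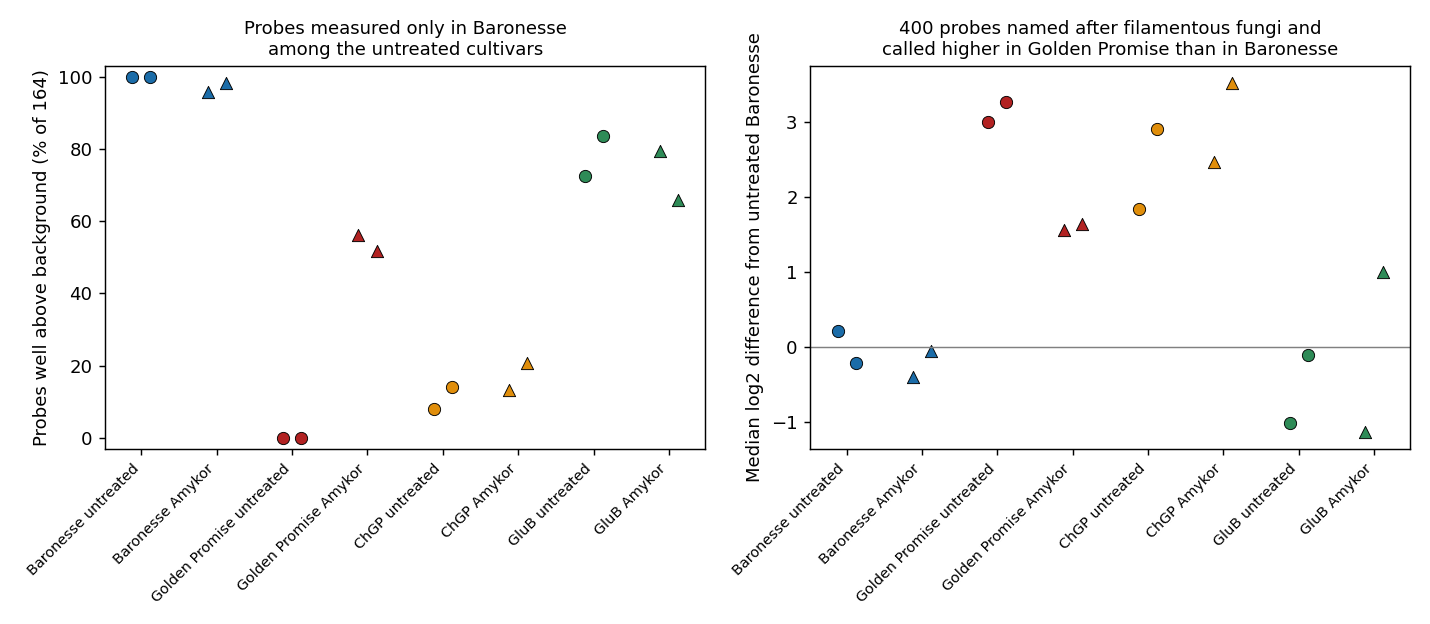
Left, percentage of 164 Baronesse-specific probes well above background on each array (vertical axis) by group; right, median log2 difference from untreated Baronesse (vertical axis) of 400 fungus-named probes that were higher in Golden Promise. Golden Promise in Amykor soil shows 56.1% and 51.8% on the left, against 0 untreated, which the choice of probes fixed, and 7.93% to 20.7% in ChGP. On the right it shows 1.56 and 1.64, against 2.99 and 3.26 untreated.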

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

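Among the tests in this part, those of Baronesse material, of induction, of sequence differences, of introgressed segments and of mixed pools were chosen after the results were seen.

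The change with Amykor differed between genotypes by a test of the difference itself, the interaction in limma. It passed for 1223 probes between Golden Promise and Baronesse, 143 between ChGP and Golden Promise and 56 between GluB and Baronesse. Each of these interactions also sets Amykor arrays of slides 1 and 3 against those of slides 3 and 5. With slide as a block 875, 88 and 82 passed, 593, 77 and 25 of them also without it. Leaving out 1 array gave 220 to 2672, 88 to 294 and 2 to 2002, lowest without the second untreated Golden Promise (first 2) or Baronesse array and highest without the first GluB Amykor array. On the compared groups alone the GluB interaction called 0 probes (3524 at an unadjusted p under 0.05). As the Amykor change in Golden Promise minus that in Baronesse, the named probes it singled out were the cation/hydrogen exchanger (35_3328, 8.307, adjusted p = 9.2e-06), Ran-1 (35_14667, 8.145, 2.4e-07), a PR5K receptor kinase (35_25987, 6.65, 0.031) and the cysteine proteinase (35_10969, 6.439, 1.4e-06). Others were the flavonol sulfotransferase (35_4431, 6.091, 0.011), MLA7 (35_19737, 6.0, 0.010), the protein kinase (35_5850, 5.787, 5.1e-05), an RNA-binding protein (35_50341, 5.076, 0.031), cysteine synthase (35_8511, 3.973, 0.049) and the UDP-glucosyltransferase (35_3491, -3.222, 0.05). At 35_3328, 35_14667, 35_25987, 35_10969, 35_4431 and 35_5850 untreated Golden Promise had 0 of 2 arrays well above background, and at 35_3491 untreated Baronesse had 0 of 2, so the sizes of these depend on the background level. At 35_50341 and 35_8511 the difference came from falls in Baronesse (-5.49 and -4.84), with -0.41 and -0.87 in Golden Promise. At 35_50341, 1 of 2 Baronesse Amykor arrays was well above background.

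As the change in ChGP minus that in Golden Promise, the same test singled out 35_3328 (-8.088, 1.2e-05), 35_14667 (-8.017, 1.9e-07), 35_5850 (-7.024, 1.3e-05), 35_10969 (-6.962, 7.4e-07) and MLA7 (35_2871, -6.582, 0.038). It also passed for 35_19737 (-6.071, 0.017), 35_4431 (-6.011, 0.022), MLA6-2 (35_2872, -5.961, 1.6e-05), an NB-ARC protein (35_28650, -5.729, 1.5e-04) and a zinc finger protein (35_49564, -5.291, 0.011). Between GluB and Baronesse it passed for the receptor-like kinase 35_5301 (-1.983, 0.047). Of the probes singled out between ChGP and Golden Promise, 35_19737 was well above background on all 16 arrays. At the others no ChGP and no untreated Golden Promise array was, so the sizes are not measured. The rise in Golden Promise was at least 44.2-fold (35_49564) to at least 342-fold (35_3328). Each soil had 2 arrays per genotype.

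Both Golden Promise arrays from Amykor soil showed signal at the 164 probes measured in untreated Baronesse and dark in untreated Golden Promise: 83 were well above background on both, at a median of 17.5% of the Baronesse level (quartiles 14.1 and 21.9). Over all 164 the medians on the arrays were 9.40% and 9.65%. Baronesse material would put all these probes at 1 fraction, yet 37.2% lay under a twentieth of the Baronesse level on both arrays (40.2% of the 82 brighter ones), which argues against it as the whole cause. Induction by Amykor in the Golden Promise background is argued against by ChGP, whose median change over the 83 probes was -0.14 (quartiles -0.22 and 0.58), against 4.07 (2.95 and 6.26) in Golden Promise. The rise in Golden Promise was fixed by the choice of these probes, so only the ChGP value bears on induction. Barley material from outside the 4 genotypes in both pools is a candidate: 35 probes were well above background on these 2 arrays and on no others, against 22 for Baronesse in Amykor soil, the next highest group. This passed the bound set for it only narrowly. A response of Golden Promise that ChGP does not share would also give such probes, stays open, and was not tested. Of all probes called with Amykor in Golden Promise, 523 of 561 rises and 146 of 153 falls went in the direction of untreated Baronesse. Both differences share the untreated Golden Promise arrays, which favours this direction. GluB material was not tested as a source, although the GluB Amykor arrays lay on the same slides 1 and 3. Of 20 Baronesse probes at background on all GluB arrays, 6 were well above background on both Golden Promise Amykor arrays. The 167 probes specific to untreated Golden Promise were at medians of 83.3% and 79.7% of its level on these arrays, against 92.3% to 94.9% in ChGP.

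The fungus-named probes called higher in Golden Promise (400 with values on all arrays) had medians of 2.99 and 3.26 on the untreated Golden Promise arrays against untreated Baronesse, and of 1.83 to 3.51 on the ChGP arrays. Barley sequence differences between the cultivars would keep replicate pools level, but the untreated ChGP replicates differed by a median of -1.03 (highest of 100 matched random lists 0.119), which argues against them as the whole cause. RNA of a fungus on the leaves is a candidate explanation: deviations from the group means correlated between the probes at 0.547 on average, against 0.0396 in the highest random list. The species and whether cultivars differed in infection were not tested, and field position was not given in the sources used here.

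GluB lay on the Golden Promise side at 137 of 331 probes that separate the parents in untreated soil and at 131 in Amykor soil, 116 of them in both. Pools mixing plants of both parental types would put all probes of 1 parent at 1 fraction of its level, yet GluB lay at both ends in both soils. Of the 164 Baronesse probes, 51 lay at or below 20 percent of the Baronesse level and 31 at or above 80 percent. Of the 167 Golden Promise probes, 81 and 24 did (48.5% and 14.4%; 34 and 15 of the 83 brighter ones), which argues against such a mixture as the whole cause. Introgressed Golden Promise segments in a Baronesse background cannot be told apart from other causes here: 89.1% of the probes lay with the same parent in both soils, against 51.8% if independent, just short of the 90 percent set for them. What keeps them open is that the probes have no map positions here. Pools of plants that differ from each other in their segments were not tested, as the pools have no values of single plants.

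Other splits of the compared arrays were fitted alone. Between Golden Promise and Baronesse 6557 probes were called, the highest other split called 0, and 1 of 35 splits had as many. GluB and Baronesse gave 1527 (highest other 0, 1 of 35), and Amykor 239 (highest other 1, 1 of 100 drawn, not balanced over genotypes). This argues against chance without excluding it, as 35 splits allow no share under 1 of 35. Other splits of a genotype pair also hold the genotype difference in their spread, and the Amykor split goes with slide. Between ChGP and Golden Promise the splits alone do not argue against chance: 2 of 35 gave as many, the real one with 142 and the split by soil with 207. Soil is a factor of the design and went together with slide, and with slide as a block 291 probes passed between the genotypes in the model of all arrays. From separate arrays, the soils shared 64 of their calls (1.3 if independent), 62 of the same sign, which argues against chance for these.

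Several tests were changed after a first result. Induction was first measured as the share of the 83 probes on in both ChGP Amykor arrays, which was 14.5% and left it open. The test of sequence differences first took all 8 groups (GluB in Amykor soil, -2.23). Before fungus-named probes were left out of the parent-separating ones (364 then), 90.1% lay with the same parent in both soils, past the bound. Mixed pools were first tested by the share of probes well between the parental levels (over 20 and under 80 percent of the brighter parent's level), which was 32.1% then and 35.05% after, and left them open.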

How the results depend on the processing

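The fits without both Golden Promise or both GluB Amykor arrays, and for lists the slide block and leaving out fungus-named or wrongly matched probes, were tests chosen after the results were seen. For single probes, the fits without both arrays compared a genotype pair in untreated soil alone (2 arrays against 2), and Amykor over the remaining genotypes. Calls lost or reversed there mix the arrays left out, the change of soil or genotypes and the smaller number of arrays. Signal over background limits the dim end: 69.6% to 77.4% of the probes were well above background per array, and folds against dark groups are bounds. Where an array was left out, the lone array of its group was assumed to vary like the others. Unless a sentence names one, the cause was not tested. GluB calls lay in the Golden Promise direction in 56.5% or more with split controls, without any 1 array and on probes well above background on all 16 arrays. Only the split controls separate the Baronesse arrays, and they still share the Baronesse genotype. Without 1 array the share was 82.5% to 91.5%, against 86.6% from shared controls alone in simulations, so it adds no support for a common direction. With replicate number as a block, 10174, 421, 4567 and 1130 probes passed in the 4 comparisons over all arrays. The numbers marked a shared slide in untreated soil (slides 2 and 4), but not over all groups. Replicate differences of 28 pairs of groups correlated at -0.22 to 0.34, 11 of them over 0.1. Pairs of groups on the same slide were at 0.04 to 0.33, a pairing that the main model left out and the slide block took up.

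Normexp background correction called 3076 probes between Golden Promise and Baronesse (3123 in untreated and 1264 in Amykor soil), 93 between ChGP and Golden Promise (12 and 55) and 832 between GluB and Baronesse (266 and 535). For Amykor it called 74 over all, 7 in Baronesse, 25 in Golden Promise, 1 in ChGP and 0 in GluB (1247 and 450 at an unadjusted p under 0.05 in limma). For the interactions it called 37 (Golden Promise minus Baronesse), 1 (ChGP minus Golden Promise) and 0 (GluB minus Baronesse), with 2974 and 1639 unadjusted for the last 2. It reversed 6 named genes between ChGP and Golden Promise: 35_4685 (-0.171), 35_14442 (-0.304), 35_30819 (-0.369), 35_13933 (-0.208), 35_13910 (-0.089) and 35_613 (-0.219). Median shifts over 0.1 with it were -0.20 between ChGP and Golden Promise (-0.37 in untreated soil) and -0.11 between GluB and Baronesse (-0.13 in untreated soil). Between Golden Promise and Baronesse they were 0.37 in untreated and -0.26 in Amykor soil, for Amykor 0.17 in Baronesse, -0.39 in Golden Promise and 0.18 in GluB, and for the first 2 interactions -0.55 and 0.38. The deposited values shifted the median by -0.13 for Amykor in GluB, -0.16 between GluB and Baronesse in Amykor soil and -0.22 for their interaction. The share of higher calls went from 42.3% to 31.2% (ChGP) and from 44.0% to 54.1% (GluB) with normexp, and from 62.4% to 73.0% (Amykor) with the deposited values.

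The 2-fold threshold, which passes fewer probes by construction, left 3648, 257, 1321 and 167 in the 4 comparisons, 432 for Amykor in Baronesse, 4513 and 2604 between Golden Promise and Baronesse in untreated and Amykor soil and 1904 between GluB and Baronesse in Amykor soil. Probes well above background on all 16 arrays, a smaller set, gave 211 between ChGP and Golden Promise (174 in Amykor soil), 0 for Amykor in GluB (1642 unadjusted), and 46 and 220 for the ChGP and GluB interactions. Without a filter on dim probes, Amykor counts were 528 over all, 449 in Baronesse, 450 in Golden Promise, 23 in ChGP and 4 in GluB, and 513 and 19 for the Golden Promise and GluB interactions.

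Fits on only the compared groups, with fewer arrays, called 1674 between GluB and Baronesse (678 in untreated, 163 in Amykor soil), 0 between ChGP and Golden Promise in untreated soil (2950 unadjusted), 0 for Amykor in Baronesse (5287), 1168 in Golden Promise, 8 in ChGP, 0 in GluB (985), and 0 for the GluB interaction (3524). Array weights gave 2435 between GluB and Baronesse (3159 and 825 by soil), 151 and 862 between ChGP and Golden Promise by soil, 3062 for Amykor in Golden Promise, and 2674, 330 and 8 for the interactions. A trended and robust spread gave 71 for Amykor in ChGP, 0 in GluB (2045 unadjusted) and 241 for the GluB interaction, and quantile scaling 7 in GluB. The deposited values gave 336 in Baronesse, 11 in GluB, and 429 and 26 for the Golden Promise and GluB interactions.

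With slide as a block, Amykor called 228, ChGP against Golden Promise 58 in untreated and 177 in Amykor soil, and the ChGP interaction 88. Scan date as a block gave 535 for Amykor, 467 in Baronesse, 18 in ChGP and 3 in GluB, 264 and 2785 for ChGP and GluB against their cultivars in Amykor soil, and 678 and 27 for the Golden Promise and GluB interactions. Pool as a block gave 402 in Baronesse, 26 in ChGP, 2 in GluB, 235 between ChGP and Golden Promise in Amykor soil, and 623 and 12 for the same interactions.

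Without both Golden Promise Amykor arrays, 68 probes passed between ChGP and Golden Promise and 137 for Amykor, and 8 and 4 gene lists passed for Golden Promise against Baronesse and for Amykor. Named genes that reversed were 35_3328 (-0.031), 35_19737 (-0.058), 35_4309 (-0.188) and 35_2872 (-0.075) for Amykor, and 35_15034 (0.094), 35_37673 (0.826), 35_19736 (0.268) and 35_19737 (0.304) between ChGP and Golden Promise. Without both GluB Amykor arrays, 1777 passed between GluB and Baronesse and 2098 for Amykor.

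Of the 4, 6, 5 and 1 lists that passed camera as first fixed in the 4 comparisons, 0, 0, 0 and 0 passed with an estimated correlation. By fry in 1 direction, 1 passed for ChGP, 8 for GluB and 0 for Amykor (16, 23 and 23 in its mixed test), and with 1 probe per product 2 for Amykor. Without the wrongly matched probes 6, 6, 6 and 1 passed.

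Leaving out 1 array gave ranges of 6999 to 10783 between Golden Promise and Baronesse (4595 to 10075 in untreated, 2304 to 6140 in Amykor soil), 260 to 545 between ChGP and Golden Promise (26 to 200, 188 to 592) and 2162 to 6237 between GluB and Baronesse (569 to 1777, 2717 to 6403). For Amykor they were 392 to 1644 over all, 38 to 2009 in Baronesse, 197 to 1680 in Golden Promise, 3 to 128 in ChGP and 1 to 862 in GluB. The interactions ranged over 220 to 2672, 88 to 294 and 2 to 2002, and the share of GluB calls in the Golden Promise direction over 82.5% to 91.5%. The highest counts all came without a GluB Amykor array.

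Among the named genes, 77 between Golden Promise and Baronesse lost 9 calls with normexp, 3 with the 2-fold threshold, 1 without both Golden Promise Amykor arrays (35_8616) and 0 elsewhere. Of 45 between ChGP and Golden Promise, 30 fell short without both Golden Promise Amykor arrays (4 with the sign reversed), 24 with normexp (6 reversed), 13 with the slide block, 13 without some array, and 7 or fewer in each other setting. Of 54 between GluB and Baronesse, 19 fell short with normexp and 4 or fewer elsewhere. Of 60 for Amykor, 52 fell short with normexp, 42 without both Golden Promise Amykor arrays (4 reversed), 35 with the slide block, 27 with the 2-fold threshold, 18 without some array, and 13 or fewer elsewhere.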

Other observations

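Nitrogen genes were higher in Golden Promise in 22 of 127 and lower in 18 (22 and 18 alone, adjusted p = 0.55), such as a peptide transporter (35_2635, 2.14 ± 0.12) and an amino acid permease (35_22604, -1.54 ± 0.19). With Amykor 1 was higher and 4 lower (2 and 6 alone, 0.51), among them a peptide transporter (35_240, -0.45 ± 0.08), while an amino acid permease rose (35_20416, 0.52 ± 0.10), neither passing under the slide block (0.081 and 0.12). Of the Amykor probes named in this part, 0 passed without both Golden Promise Amykor arrays: these 2 were at -0.43 and 0.34 there (adjusted p of 0.097 and 0.26). Peroxidases and redox genes (26 higher, 49 lower of 211, 27 and 50 alone, 0.74) included catalase 2 (35_49711, 1.29 ± 0.08), and with Amykor (5 and 6, 0.74) peroxidase 4 (35_14349, 1.10 ± 0.20, 6 of 8 Amykor and 2 of 8 untreated arrays well above background, slide block 0.10; 0.53 and 0.34 without those arrays). Calvin cycle genes were lower in Golden Promise in 8 of 38 and higher in 2 (15 and 3 alone, median -0.30, adjusted p = 0.070, 0.014 with a slide block). They included phosphoribulokinase (35_14461, -0.68 ± 0.13) and a rubisco-binding protein (35_360, 0.85 ± 0.12), and sedoheptulose bisphosphatase rose with Amykor (35_15187, 0.40 ± 0.06, slide block 0.053; 0.24 and 0.22 without those arrays).

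WRKY and NAC factors (11 higher, 10 lower of 70, 11 and 10 alone) had an adjusted p of 0.21, and of 0.0013 without both Golden Promise Amykor arrays, a test chosen after the results were seen. WRKY45 (35_4766) differed by 1.12 ± 0.13 and WRKY6 (35_25884) by -0.92 ± 0.12, the latter higher with Amykor (0.50 ± 0.09, slide block 0.062; 0.41 and 0.14 without both Golden Promise Amykor arrays). Jasmonate genes (11 and 11 of 48, 13 and 12 alone, 0.9997) included a 23 kDa jasmonate-induced protein (35_38618, 2.71 ± 0.20) and lipoxygenase 1 (35_14194, 1.89 ± 0.25). Clock and flowering genes (4 and 5 of 44, 4 and 5 alone, 0.92) included MADS26 (35_20622, 1.15 ± 0.10) and a flowering locus T-like protein (35_8616, -1.35 ± 0.25). The latter was at -0.34 (adjusted p = 0.52) without both Golden Promise Amykor arrays, in untreated soil alone. With Amykor another MADS26 probe was higher (35_27943, 0.59 ± 0.07, slide block 0.015, and 0.47 with an adjusted p of 0.068 without both Golden Promise Amykor arrays). Transposable element probes (28 and 20 of 172, 27 and 20 alone, 0.31) included 35_31984, at least 26.0-fold higher in Golden Promise. Heat shock proteins (24 and 30 of 214, 22 and 28 alone) had an adjusted p of 0.91 between the cultivars.

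Anther and pollen genes, markers of flower tissue, were higher in Golden Promise in 4 of 32 and lower in 4 (4 and 3 alone, 0.56), with a pollen allergen (35_7860) at 2.28 ± 0.16, and held 0 higher and 2 lower with Amykor (1 and 2 alone, 0.20). Grain storage genes held 0 higher and 0 lower of 41 between ChGP and Golden Promise in limma (4 at an unadjusted p under 0.05, adjusted p = 0.76) and 2 and 2 with Amykor (0.74). Of the (1,3-1,4)-beta-glucanase list, the array held 3 probes, and 0 were well above background often enough to be tested.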
